A study of Danio rerio with 96 samples.

How the data were processed

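The data were 96 single-channel (Cy3) zebrafish arrays, 1 per pooled liver RNA sample, in 32 groups of 3. Adult fish had been held for 6 weeks with venlafaxine (VEN, an antidepressant), acetaminophen (ACE, an analgesic), gemfibrozil (GEM, a fibrate lipid-lowering drug), carbamazepine (CBZ, an anticonvulsant), a mixture of equal concentrations of the 4 drugs (MIX) or diluted wastewater effluent (WWE). The low dose was 0.5 µg/L or 5% effluent and the high dose 10 µg/L or 10% effluent. The treatment protocol gives 25% for the high effluent dose, so its dilution is uncertain. The labels do not say whether the MIX concentration is per drug or in total. Tanks held 50 fish, were dosed every 3 days after a 90% water change, and stood in triplicate. Livers of 10 to 20 fish per sex were stripped from the gut and pooled. The labels assign the arrays to 4 experiments with their own controls: VEN-ACE (water), GEM-MIX (DMSO up to 0.004%), CBZ (DMSO) and WWE (water).

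Per the file headers, the deposited scanner files hold spot intensity from Agilent Feature Extraction 10.7.3.1, with spatial background detrending and multiplicative detrending inside each array and no scaling between arrays. The series matrix holds intensity that, per the labels, the authors set to at least 5 and scaled with a non-linear curve on rank-invariant probes, not log transformed. In 21 of its columns the lowest value was exactly 5, so the floor there had not been scaled. It was used as an alternative only. The authors' design text gives the rest of their path as log transformation, median centering, a two-factor test per experiment (sex, treatment and their interaction, permutation p under 0.01) and then a rank product test for each dose and sex with a false discovery rate of up to 10%.

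Each array had 45220 spots with 43603 distinct probes after the controls were left out. RefSeq accessions, current symbols and older symbols gave 24873 probes 1 symbol, 1065 had several and 17665 had none. Probes with several names or none were kept as features of their own. Processed intensity below 5 was set to 5. Every array was then scaled with a smoothing spline (8 degrees of freedom) on probes with an invariant rank, 1089 to 3947 per array, against the median of all 96 arrays, and log2 transformed. Spots with an outlier mark were left out, a median of 20 probes per array and 978 at most, and no spot was saturated. The scaled values had a correlation across probes of 0.984 or more with the authors' table on every array, with a median of 0.998. The correlation of their deviations from the mean of the arrays, over 11428 probes, was 0.796 or more with a median of 0.979. A gene was represented by its brightest probe. A feature was tested in an experiment when it was well above background on all 3 arrays of at least 1 group and missing on 1 array at most. Where no array of a group was well above background, a fold change is given as at least N-fold, with those arrays set to at least the lowest intensity marked well above background on them.

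Models were fitted per experiment in limma 3.58.1 under R 4.3.3, with 1 mean for each sex and treatment group and moderated variances. The effect of an exposure within a sex was tested with a moderated F over both doses, Benjamini-Hochberg adjusted at 0.05, and each dose was then compared with control, adjusted within the contrast. "Called" means an adjusted p below 0.05 in that F test. Counts that rose or fell (were higher or lower) at a dose are features with an adjusted p below 0.05 in that dose's own contrast, whether or not the F test called them, so they are no breakdown of the called features. The same design gave the interaction with sex, and the direct comparison of the exposures that shared controls (VEN with ACE, GEM with MIX). The sex difference used the 24 control arrays with experiment as a block. All gene p-values are limma's, two-sided and adjusted, and ± is the SD of 3 arrays unless another n is given. Both values of a fold change are log2 intensity.

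The lists were 21 pathway lists and 9 lists of markers of other cells and tissues. The pathway lists were acute phase and complement, bile acids, cell cycle, cholesterol synthesis, circadian clock, cytochrome P450 and other phase I enzymes, egg yolk proteins and oestrogen receptors, fatty acid synthesis, fatty acid oxidation, glucocorticoid response, gluconeogenesis, growth hormone and IGF, heat shock, lipoproteins, mitochondrial respiratory chain, monoamines, oxidative stress, phase II enzymes and transporters, ribosomal proteins, steroids and thyroid. The marker lists were adipocyte and muscle, biliary and endothelial, endocrine pancreas, exocrine pancreas, erythrocyte, intestine, macrophage and lymphocyte, ovary, and testis. They were tested with camera (preset correlation 0.01) and adjusted over 504 pathway and 216 marker tests, and again with an estimated correlation. A marker score is the mean log2 intensity of a list on an array.

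Before the data were examined, the groups, tests, lists, alternatives and the rule for named genes were fixed. For each exposure and sex the rule takes the 5 largest rises and 5 largest falls at the high dose and 3 of each at the low dose. These are symbols past both tests with all 3 exposed arrays on one side of all 3 controls. Where none passed, the 3 symbols with the smallest p are given as not passing. For interactions and direct comparisons it takes the 5 smallest adjusted p, for sex the 5 largest differences each way, and for lists the members with the smallest p. It also takes 12 genes in every case: vtg1, esr1, cyp1a, cyp3a65, cyp7a1, cpt1b, ehhadh, fabp10a, hmgcra, sqlea, per1a and slc6a4a. A contrast of each exposure over both sexes and doses was added after the data had been seen.

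The alternatives were 75th percentile and quantile scaling, normexp background correction (offset 50), the authors' value table, a strict filter (well above background on every array of the experiment), no filter, every probe on its own, slide, scan day and replicate number as blocks, the tank as a random block, the arrays of 1 sex only, leaving out each array, and the methods' two-factor test with rank product (1000 permutations), with an ordinary F in place of its permutation p. Marker scores as covariates and leaving out 8 arrays with outlying ovary markers were added later. These 8 were Female WWE control 3 and the male arrays with an ovary score above the female median of 11.45. The replicate block takes the replicate number as a fixed block within an experiment. The rank product was run only on features with p under 0.01 in the two-factor test of the same arrays. Its counts are therefore no independent second test, and its false discovery rate does not cover that selection. A simulation drew arrays with independent normal noise and no slide, scan day or tank differences, and 200 changes per comparison were added. Real arrays hold such differences, so its rates are those of an ideal case. In the VEN and GEM designs 6% to 16% of 1-unit changes and 80% to 100% of 3-unit and 4-unit changes were called. In the CBZ and WWE designs 0% to 2% of 1-unit and 52% to 80% of 3-unit and 4-unit changes were called. There were 2 to 9 false calls per comparison. Extraction and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.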

Results

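The series compared the liver transcripts of adult zebrafish after 6 weeks in water with low levels of human drugs or wastewater effluent. It held 96 arrays from 4 experiments, and each group had 3 pooled liver samples of 1 sex. The VEN-ACE experiment had 30 arrays (control, VEN low and high, ACE low and high, in each sex), GEM-MIX had 30, and CBZ and WWE had 18 each. The arrays lay on 26 slides scanned on 6 days. The share of probes well above background was 41.7% to 77.5% per array with a median of 56.6%, and the 75th percentile of the unscaled intensity was 58.5 to 774. With 3 arrays per group, their number limits the precision of every value. Depending on the experiment, 18647 to 21076 features were tested.

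**Figure D1:**
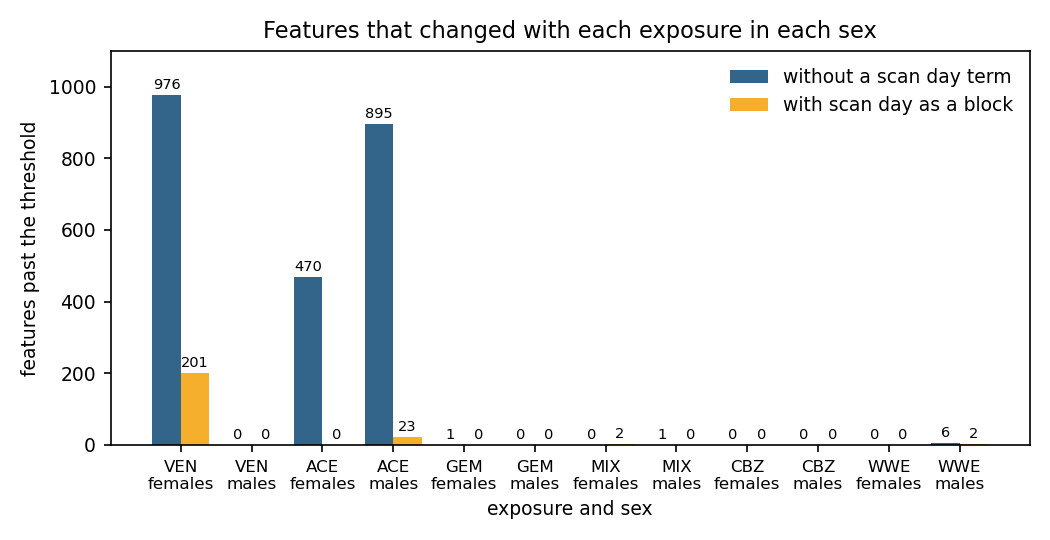
Bars give the number of features called for each exposure in each sex, without and with scan day as a block (x axis, exposure and sex; y axis, features with an adjusted p below 0.05). With that block the high dose of VEN in females rests on a lone array. VEN in females (976) and ACE in both sexes (470 and 895) had most of the calls, and these fell to 201, 0 and 23 with scan day as a block.

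The control fish answered how female and male liver pools differ when unexposed, with ovary and testis markers among the differences. The egg yolk genes were far higher in females, with a mean of 13.43 ± 0.95 log2 intensity for vtg2 (vitellogenin, a yolk precursor) against 5.55 ± 1.45 in males (SD, n = 12 each), a difference of 7.88 (SE 0.41, adjusted p = 4.17e-12). The oestrogen receptor gene esr1 had 11.41 ± 0.68 against 6.97 ± 0.60 (difference 4.44, adjusted p = 1.79e-12), and vtg1 differed by 1.66 (adjusted p = 5.75e-05). The largest differences towards females were dnal4b, a dynein light chain, at 8.25 (SE 0.27, adjusted p = 3.13e-15), vtg2, zbtb24 at 7.66, nots, a liver aspartic protease of female fish, at 6.92, and the P450 gene cyp2k6 at 6.82. Males had more hsd17b3, a testosterone-forming enzyme, with 12.02 ± 1.01 against 4.60 ± 1.58 in females (n = 12 each, difference -7.42, adjusted p = 2.12e-12). They also had more cyp2k-like (-6.80), tuba7l (-5.51), efhc2 (-4.98) and the carotenoid oxygenase gene bco2b (-4.94). The last 3 stood beside testis markers that were lower in females by a median of -1.5 (10 of 15 called; adjusted p = 4.17e-05, and 0.237 with an estimated correlation), and ovary markers were higher in females by 3.77 (23 of 25 called, 22 of them higher). In all, 6767 of 19968 features were called, 3288 higher in females and 3479 higher in males, and 6342 of the 6767 had the same direction in all 4 experiments. The scan day block called 5499.

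By group, 8 of 9 egg yolk and oestrogen receptor genes were called, all higher in females (median 4.44, adjusted p = 1.35e-11). It was the single list whose call held with an estimated correlation (adjusted p = 0.0313). Acute phase and complement genes were lower in females by a median of -0.57 (24 of 46 called, all lower; adjusted p = 2.42e-07, and 0.146 with an estimated correlation). Phase II enzymes and transporters were lower by -0.58 (22 of 48 called, all lower; adjusted p = 7.16e-06, and 0.146 with an estimated correlation). Growth hormone and IGF genes were at -0.80 (8 of 14 called, adjusted p = 0.00129, and 0.171 with an estimated correlation). Cell cycle genes were at 0.96 (16 of 27 called, 15 higher; adjusted p = 0.000311, and 0.375 with an estimated correlation), beside the higher ovary markers (adjusted p = 1.66e-08, and 0.266 with an estimated correlation). Ribosomal protein genes were at 0.31 (34 of 70 called, all higher; adjusted p = 0.19 with an estimated correlation), and at 0.86 with 75th percentile and 0.23 with quantile scaling. Among the genes named in every comparison, cyp7a1, the rate-limiting enzyme of bile acid synthesis, was lower in females by -1.70 (adjusted p = 0.00474), cyp3a65 by -1.72 (adjusted p = 0.0211) and the peroxisomal enzyme ehhadh by -0.66 (adjusted p = 0.00179). The clock gene per1a was higher by 0.55 (adjusted p = 0.0237) and the serotonin transporter gene slc6a4a by 0.58 (adjusted p = 0.0258). The values for cyp1a (-0.22), cpt1b (-0.53) and fabp10a (-0.13, but 0.58 with 75th percentile scaling) did not pass. hmgcra was not among the genes tested in every experiment, and sqlea was not on the array.

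In females, VEN was tested against water controls at both doses. The transcript of abcc2, the canalicular export pump for conjugates, fell from 9.57 ± 1.05 in controls to 2.61 ± 0.69 at the low dose, at least 61-fold (log2 change -6.96, SE 0.96, adjusted p = 0.00182), and to 4.77 ± 1.79 at the high dose (-4.80, adjusted p = 0.00503; n = 3 each). At the high dose adarb1a, an RNA-editing adenosine deaminase, rose from 2.76 ± 0.24 to 7.90 ± 1.95, at least 12.6-fold (5.14, SE 0.78, adjusted p = 0.000708). The muscle gene nrap rose by 4.96 (adjusted p = 0.00101), si:ch73-364h19.1 by 4.75 (at least 8.6-fold, adjusted p = 0.000728), an uncharacterised predicted gene by 4.44 (at least 6.5-fold) and the growth factor gene gdf11 by 4.28 (at least 6.2-fold, adjusted p = 0.00538). The metalloprotease genes adam28, of whose 3 probes 1 went the other way, and bmp1a fell by 3.34 and by 3.28 (adjusted p = 0.0227 and 0.00503). The glyoxylate reductase gene grhprb fell by 3.13 and the sterol transfer gene stard3nl fell by 2.99 (adjusted p = 0.00958 and 0.0128). In the low-dose group si:ch211-272f3.3 rose by 2.40, olfml1 by 2.21 and si:ch211-122a20.1 by 2.19 (adjusted p = 0.00294, 0.0291 and 0.000209), each from no array well above background.

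Phase I enzymes were lower in females at high VEN, with 43 of 52 members lower and a median of -0.52 (adjusted p = 0.00182, and 0.973 with an estimated correlation). 1 member passed on its own, ahr1a, a receptor for aryl hydrocarbons, at 3.35 ± 0.59 against 5.59 ± 0.34 (n = 3 each, -2.24, adjusted p = 0.00204). Ovary markers were higher by a median of 1.05 at that dose (24 of 25 members; adjusted p = 0.972 with an estimated correlation), and exocrine pancreas markers by 0.67 at the low dose (24 of 28; adjusted p = 0.876 with it).

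The F test called 976 of 21076 features in VEN females, 443 with a symbol. By each dose's own contrast, whatever the F test gave, 12 rose and 1 fell at the low dose and 619 rose and 489 fell at the high dose. With 75th percentile scaling, which moved the median of all features by 0.20, the high-dose split was 1387 and 215. VEN high 1 and 3 were scanned on day 6 and the other VEN and control arrays of females on day 1. No other VEN-ACE array was scanned on day 6. In the fit with scan day as a block the high dose therefore rested on VEN high 2 alone. With scan day as a block 201 features were called, 96 of them shared. Then abcc2 at the low dose (adjusted p = 0.00371) and the 3 low-dose rises passed. The high-dose values, from VEN high 2 alone, were -4.03 for stard3nl, 3.06 for adarb1a, 2.86 for nrap, 1.33 for gdf11 and -5.23 for abcc2. With slide as a block the high-dose values turned to -0.37 for adarb1a, -1.16 for the predicted gene, -1.21 for gdf11 and 0.86 for abcc2. All low-dose arrays and their controls were scanned on day 1. Within day 1 the high dose (1 against 3, the lone array assumed to vary like the others) called 169 features. Of the 762 that passed both the F test and that dose's contrast over all days, these 4 arrays among them, 736 had the same direction, which their selection favours, with a median size of 1.67 against 2.28. The count was 165 without VEN high 1, 3375 without VEN high 2, 623 without VEN low 3, and 593, 563 and 649 without control 1, 2 and 3, and it was 2 among features well above background on every array.

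In males, no feature was called for VEN by limma (smallest adjusted p = 0.199), with 691 at an unadjusted p under 0.05. The rank product ran only on 4522 features preselected with the same arrays. It called 20 higher and 1 lower at the low dose and 0 higher and 26 lower at the high dose. The smallest p-values belonged to muscle genes at the low dose, trim55b with 5.17 ± 1.5 against 2.85 ± 0.22, the muscle phosphofructokinase gene pfkmb with 5.40 ± 2.25 against 2.38 ± 0.29, and titin, ttna, with 6.78 ± 1.95 against 2.68 ± 0.58 (n = 3 each, F-test adjusted p = 0.292, 0.322 and 0.417). Adipocyte and muscle markers went with them, 20 of 20 higher with a median of 1.44 (adjusted p = 8.42e-14, and 0.0556 with an estimated correlation). At the high dose 26 of 27 cell cycle genes were lower, by a median of -0.94 (adjusted p = 3.5e-08, and 0.973 with an estimated correlation), ccne1 with 4.69 ± 1.64 against 6.78 ± 0.83. They stood beside ovary markers that were lower by -1.76 (24 of 25; adjusted p = 0.619 with an estimated correlation). All 9 egg yolk and oestrogen receptor genes were higher, by a median of 1.15 (adjusted p = 2.61e-05, and 0.883 with an estimated correlation), vtg4 with 15.17 ± 0.77 against 13.34 ± 1.99. Heat shock genes were at 0.20 at the low dose (36 of 47 higher; adjusted p = 0.00314, and 0.973 with an estimated correlation). The count was 3 without male control 2 and 19 without male VEN low 1.

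The difference in VEN response between the sexes was tested as an interaction, which called 31 features, 12 with a symbol. The female change exceeded the male one by 2.5 (SE 0.36) for si:ch211-122a20.1 at the low dose (F-test adjusted p = 0.00416). It did so at the high dose by 2.66 for abca4a, an ABC lipid transporter, by 3.11 for cd109, a membrane protease inhibitor, and by 3.61 for the sugar transporter gene slc45a4b (F-test adjusted p = 0.0243, 0.0288 and 0.0296). For lims2, a focal adhesion gene, the difference was -3.07 at the low dose (F-test adjusted p = 0.0187). With scan day as a block the female high dose rested on VEN high 2 alone. The scan day block called 10, 5 of them shared. The count was 984 without female VEN high 2, 5 without female VEN high 1 or male VEN high 1, 6 without male VEN low 2, 7 without female VEN low 1, 8, 12 and 20 without female control 1, 2 and 3, 9 and 12 without male control 3 and 1, 12 without female VEN high 3 and 13 without male VEN high 3.

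ACE was tested against the same controls. In females at the high dose olfm3a, a secreted olfactomedin, stood at 10.15 ± 0.27 against 2.80 ± 0.43 in controls (n = 3 each, at least 60-fold; log2 change 7.35, SE 1.02, adjusted p = 0.000585). The melanin synthesis gene dct rose by 6.24 (adjusted p = 0.00656), the phosphatase subunit gene ppp2r5eb by 6.08 (0.000981), the nuclear pore gene nup93 by 5.12 (0.00777) and spata6l by 5.07 (0.0164). The largest falls were myoc at -2.68 (at least 2.7-fold), the muscle gene klhl41b at -2.29, rhbdl3 at -2.15, ndnf at -1.56 and the RNA methylation reader ythdf2 at -1.56. At the low dose olfm3a rose by 5.43 (at least 15.9-fold), the tubulin gene tubb2 by 4.10 (SE 0.58, adjusted p = 0.00548) and supt3h by 3.73 (at least 3.8-fold), while the cholesterol esterifying enzyme gene soat2 stood at 4.01 ± 1.76 against 8.56 ± 1.14 (-4.54, adjusted p = 0.0155), wu:fu71h07 at -2.75 and ftr26 at -1.93. 470 features were called, 144 with a symbol. The dose contrasts on their own gave 117 higher and 17 lower at the low dose and 598 and 35 at the high dose. The count was 253 without ACE high 2, 807 without ACE low 1, and 190, 245 and 203 without female control 1, 2 and 3.

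In males at high ACE itga11a, a collagen-binding integrin, rose from 9.33 ± 0.82 to 15.36 ± 0.79 (n = 3 each, 6.04, SE 0.98, adjusted p = 0.000621), and olfm3a rose by 6.41 (adjusted p = 0.000563), dct by 6.12, si:ch211-217k17.10 by 6.86 and the transcription elongation gene cdc73 by 6.78. For dct and cdc73 another probe went the other way. The clock gene cry3a fell by 1.93 (SE 0.45, adjusted p = 0.0109), cdk21 fell by 2.11, wu:fj59c10 by 2.15, tp53inp2a by 2.08 and si:ch211-274k16.2 by 1.81. At the low dose cyp17a, a sex steroid synthesis enzyme, stood at 8.84 ± 0.41 against 3.86 ± 1.75 (4.98, adjusted p = 0.00546), the exonuclease gene xrn2 at 5.2 (1 of its 3 probes opposite) and supt3h at 4.71 (at least 8.8-fold), while the chemokine scavenger gene ackr4a was at -2.15, bco2l at -2.11 and the cytokine gene il10 at -1.86. 895 features were called, 347 with a symbol, and the dose contrasts on their own gave 365 higher and 32 lower at the low dose and 757 and 34 at the high dose. The count was 500 without ACE high 2 and 590 without ACE high 3.

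The ACE arrays and their controls were scanned on different days. All controls were scanned on day 1, 10 ACE arrays on days 2 and 3, and 1 array of each sex, ACE low 1, on day 1. With scan day as a block 0 features were called in females (1573 at an unadjusted p under 0.05) and 23 in males, all 23 among the 895, and olfm3a at the high dose was then at 4.66 in females (adjusted p = 0.323) and 3.84 in males (0.61). Within day 1 each sex had 1 ACE low array against 3 controls, so the spread of ACE arrays could not be estimated there. Of the features that passed both the F test and that dose's contrast over all days, that array among them, 132 of 132 in females and 371 of 372 in males had the same direction, with median sizes of 1.86 and 1.78 against 2.69 and 2.74. Over the features called for ACE in either sex, the male ACE low array of slide 5 stood 0.95 from its controls, and the male VEN high array of the same slide 0.66 from the other male VEN high arrays. In 11 unexposed control arrays of GEM-MIX and CBZ (DMSO) scanned on days 2 and 3, olfm3a stood at 9.10 ± 0.75. This was near the 9.58 ± 0.63 of the 10 ACE arrays of those days and far from the 3.07 ± 0.73 of the 6 VEN-ACE controls (water). For dct these means were 14.98 ± 1.53, 15.46 ± 1.43 and 9.32 ± 1.65. Of the 28 genes named for the largest ACE changes, chosen for their distance from the VEN-ACE controls, 26 had an ACE mean nearer to that of these other controls. The exceptions were soat2 with 9.83 ± 1.23, 7.47 ± 2.72 and 9.3 ± 1.39 and myoc with 5.42 ± 1.27, 4.56 ± 1.55 and 5.33 ± 0.34, which were not tested. By the strict filter 108 and 225 features were called. For males at the low dose 75th percentile scaling moved the median of all features by -0.14.

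**Figure D2:**
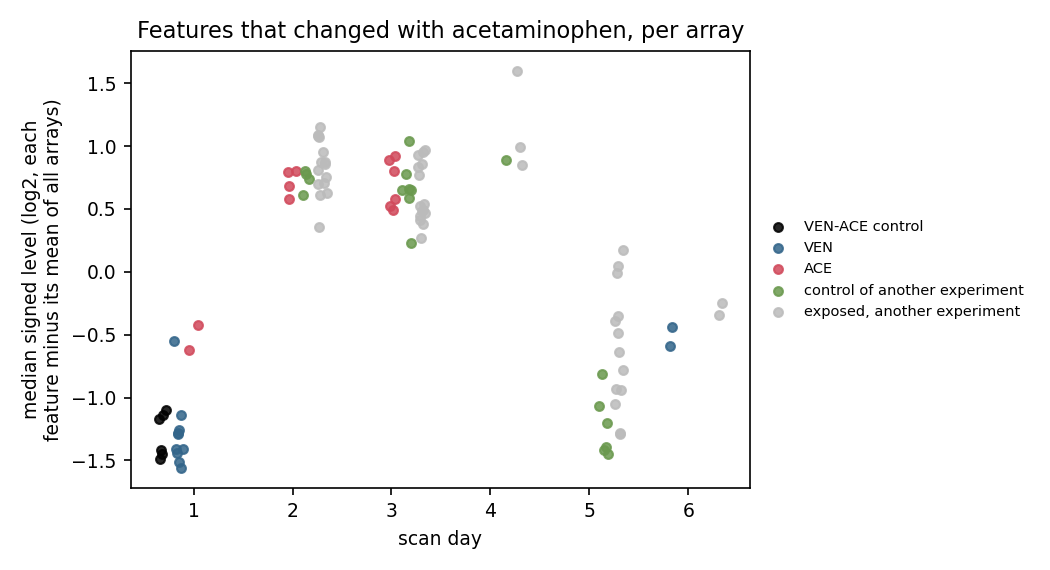
Each point is 1 array, placed by scan day (x axis) and by its median signed log2 level over the 1056 features called for ACE in either sex (y axis, log2 units, positive in the direction of the ACE change). Unexposed GEM-MIX controls of day 2 lay at 0.61 to 0.80 and ACE arrays of that day at 0.58 to 0.80, while VEN-ACE controls of day 1 lay at -1.49 to -1.1.

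Among the lists, females at low ACE had 43 of 52 phase I enzymes lower, with a median of -0.62 (adjusted p = 0.000352, and 0.973 with an estimated correlation), for example cyp2k18 with 10.32 ± 1.27 against 11.98 ± 0.60. Fatty acid oxidation genes were at -0.33 (35 of 42 lower), phase II enzymes at -0.39 (34 of 48) and acute phase genes at -0.45 (36 of 43), each with an adjusted p of 0.973 with an estimated correlation. The carnitine transferase gene cpt1b stood at 8.41 ± 2.46 against 11.96 ± 0.63 (n = 3 each, -3.55, adjusted p = 0.166). Cell cycle genes were higher by 0.95 at the low dose and 0.63 at the high dose in females and by 1.3 at the low dose in males (24 of 27 higher, adjusted p = 4.4e-08; 10 passed adjusted over the list alone). Each estimated correlation gave an adjusted p of 0.973. In each of these groups ovary markers were higher too, by 1.32, 0.81 and 2.99 (adjusted p = 0.885, 0.972 and 0.474 with an estimated correlation), and intestine markers were lower by -1.49 in high-dose females (adjusted p = 0.952 with it). In low-dose males 6 of 9 egg yolk genes were higher (median 1.91, adjusted p = 0.0419, and 0.973 with an estimated correlation), vtg5 with 15.61 ± 0.59 against 12.63 ± 1.97 (adjusted p = 0.0367). The interaction of ACE with sex called 4 features, among them nubpl, an assembly factor of respiratory complex I, whose female change exceeded the male one by 2.94 at the high dose (SE 0.46), and the ion channel gene p2rx3a at -2.45 at the low dose (F-test adjusted p = 0.0178 each). The scan day block called 2. The count was 2 without male ACE high 3 and 9 without male control 3. 75th percentile scaling moved the median of all features by 0.14 at the low dose and called 0.

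VEN and ACE share their controls and were compared directly at each dose. In females tubb2 was lower under VEN at the high dose, with 3.29 ± 0.37 against 7.59 ± 0.13 (n = 3 each, -4.29, F-test adjusted p = 1.72e-05), and so were abcc2 (-6.62, at least 48.2-fold) and xrn2 (-5.49, 1 of its 3 probes opposite) at the low dose. The genes abca4a (2.76, at least 2.2-fold) and cd109 (4.05, at least 5.3-fold) were higher under VEN at the high dose. In males si:dkey-211g8.1 (-2.14), supt3h (-5.02, at least 15.6-fold), pdcl (-3.80), dcbld1 (-4.19) and dok6 (-3.48) were lower under VEN (F-test adjusted p = 8.24e-05 or less). In all 2410 features differed in females and 2141 in males, and 58 and 5 with scan day as a block, 48 and 5 of them shared, and with slide as a block dcbld1 was at 0.07. Within day 1 the low dose had 3 VEN arrays against 1 ACE array in each sex, so the spread of ACE arrays could not be estimated there. Of the 554 and 925 features past both the F test and that contrast over all days, 554 and 923 kept their direction. Their selection with these same arrays favours this. Median sizes were 1.66 in females and 2.31 in males, against 2.32 and 2.72 over all days. In females the count was 1564 without ACE high 2, 3644 without ACE low 1, 1526 without ACE low 2, 4072 without VEN high 2 and 1535 without VEN low 3. In males it was 1405 without VEN high 1 and 1235 without VEN high 2. 75th percentile scaling moved the median of all features by 0.22 in females at the high dose, where 1389 were then higher and 449 lower under VEN against 683 and 884, and by 0.13 and 0.15 in males.

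GEM was tested against DMSO controls. In females all 3 low-dose arrays were scanned on day 3 and the controls on days 2 and 4, so they shared no scan day. The rank product, for GEM and MIX alike, ran on 1348 features preselected with the same arrays. In females 1 feature without a symbol was called, and the rank product called 39 higher and 69 lower at the low dose and 19 and 18 at the high dose. The named genes with the smallest p were lower at the low dose: slc6a22.1 with 9.0 ± 0.30 against 10.93 ± 0.51, the cell cycle inhibitor hbp1 with 10.21 ± 0.30 against 12.02 ± 0.31, and the choline kinase gene chkb with 11.48 ± 0.65 against 13.55 ± 0.39 (n = 3 each). They did not pass the F test (adjusted p = 0.0596 each). In males limma called 0 features (476 at an unadjusted p under 0.05), and the rank product called 24 higher and 15 lower at the low dose and 23 and 15 at the high dose. Closest were kctd12.1 at the high dose with 11.54 ± 0.24 against 10.01 ± 0.21 (F-test adjusted p = 0.249), slc16a10, an aromatic amino acid transporter, at the low dose with 14.80 ± 0.06 against 13.54 ± 0.39, and the cryptochrome gene cry5 with 6.19 ± 0.64 against 8.10 ± 0.30 (n = 3 each, F-test adjusted p = 0.389 each). The interaction with sex called 0 features in limma (394 at an unadjusted p under 0.05), and the two-factor interaction in GEM-MIX called 0 after adjustment and 71 at p under 0.01. In females the count was 0 without control 1 or 3, 2 without control 2, 11 without GEM high 2, 4 without GEM high 3, 8 without GEM low 3 and 0 with scan day as a block.

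Clock genes were lower in GEM males, with 19 of 26 lower at the low dose (median -0.43, adjusted p = 2.5e-05, and 0.422 with an estimated correlation) and 16 of 26 at the high dose (-0.23, adjusted p = 0.00182, and 0.671 with an estimated correlation). At the low dose 9 passed adjusted over the list alone and 0 over all genes, among them cry5, cry3b (8.32 ± 0.26 against 9.66 ± 0.39) and per2 (6.90 ± 1.09 against 9.25 ± 1.06). Fatty acid oxidation genes, the targets of the receptor that fibrates activate in mammals, were lower in males at the high dose in 38 of 42 cases (median -0.36, adjusted p = 1.14e-07, and 0.422 with an estimated correlation), with cpt1ab at 9.01 ± 0.46 against 10.16 ± 0.33. In high-dose females 29 of 42 were lower (-0.18, adjusted p = 0.0115, and 0.973 with an estimated correlation), and pdk2a at -2.83 and cpt1b at -2.5 passed adjusted over the list alone (adjusted p = 0.00837 each). Phase I enzymes were lower in high-dose males and females (medians -0.23 and -0.17), with cyp2x9 past the list alone in both. Cholesterol synthesis genes were higher at the low dose in females (0.35, mvda at 10.38 ± 0.26 against 8.41 ± 0.93) and males (0.64), and all of these had an adjusted p of 0.973 with an estimated correlation. Beside these lists 5 tests of markers of other tissues were called in GEM females and 8 in GEM males. Ovary markers were higher in GEM males by 1.28 and 1.53 (adjusted p = 0.876 each with an estimated correlation), and cell cycle genes by 0.55 and 0.48 (adjusted p = 0.00101 and 0.0032, and 0.973 each with an estimated correlation).

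**Figure D3:**
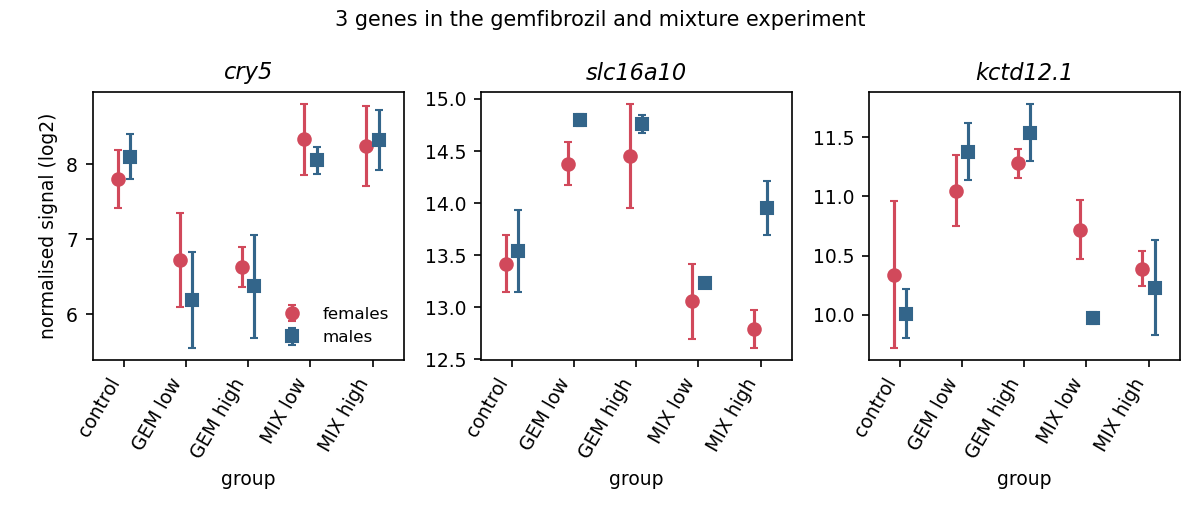
Group means with SD (n = 3) of cry5, slc16a10 and kctd12.1 in the GEM-MIX experiment (x axis, treatment group; y axis, log2 intensity). In males cry5 had 8.10 in controls, 6.19 and 6.37 at low and high GEM, and 8.05 and 8.32 at low and high MIX.

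The mixture was compared with the same DMSO controls. In males 1 feature was called, ucmab, a cartilage matrix gene, with 6.88 ± 0.75 at the low dose against 2.68 ± 0.50 (n = 3 each, at least 9.1-fold; 4.20, SE 0.61, adjusted p = 0.0106), and 1512 had an unadjusted p under 0.05 (rank product 24 higher and 1 lower, then 16 and 0). In females limma called 0 (1172 at an unadjusted p under 0.05), and the rank product 33 higher and 5 lower at the low dose and 5 and 4 at the high dose. Closest were trim62.1 with 4.76 ± 0.48 against 6.76 ± 0.22, the activin subunit gene inhbaa with 3.01 ± 0.70 against 5.63 ± 0.86 and the phospholipid enzyme gene pisd with 9.54 ± 1.03 against 12.12 ± 1.2 (n = 3 each, F-test adjusted p = 0.234, 0.71 and 0.71). Ovary markers were higher in MIX males by 3.31 at the low dose and 3.41 at the high dose (adjusted p = 0.474 and 0.247 with an estimated correlation; btg4 with 9.48 ± 1.98 against 4.33 ± 0.07). Beside them cell cycle genes were higher by 0.83 and 0.85 (adjusted p = 1.11e-06 and 3.5e-08, and 0.973 each with an estimated correlation) and fatty acid oxidation genes lower by -0.31 and -0.19 (0.973 each with an estimated correlation). In low-dose males 25 of 26 clock genes were lower (-0.33, adjusted p = 0.0181, and 0.973 with an estimated correlation). In high-dose females phase I enzymes were higher by 0.26 and phase II enzymes by 0.20 (0.973 each with an estimated correlation), beside exocrine pancreas markers lower by -0.87 (adjusted p = 0.619 with it). The interaction with sex called 0 (541 at an unadjusted p under 0.05). With scan day as a block ucmab had an F-test adjusted p of 0.126, and 2 other features were called in females, pisd among them (F-test adjusted p = 0.000718). The count in males was 381 without MIX low 3, 23 without MIX low 2 and 0 without MIX low 1. In females it was 195 without MIX low 3 and 2 without MIX high 1, and for the interaction it was 216 without male MIX low 3.

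GEM alone and the mixture that contains it were compared at matched nominal doses. In females the low-dose GEM arrays were all scanned on day 3 and the low-dose MIX arrays on days 2 and 4, so they shared no scan day. In females cyp2k-like, which was higher in male than female controls, stood at 3.33 ± 0.90 at high GEM against 7.06 ± 0.49 at high MIX (n = 3 each, -3.73, F-test adjusted p = 0.000281). In females slc16a10 was higher under GEM by 1.66 (F-test adjusted p = 0.000508), trim62.1 by 2.80 at the low dose and the ubiquitin ligase gene cbl by 2.1, while msrb3, a methionine sulfoxide reductase, was lower by -1.38. In males ucmab was lower under GEM (-4.51, at least 10.9-fold) and LOC137488017 higher (2.99; F-test adjusted p = 0.00387 each). Males also had higher slc16a10 (1.57) and kctd12.1 (1.41) at the low dose and lower cry5 (-1.95) at the high dose under GEM (F-test adjusted p = 0.0075 each). 247 features were called in females and 14 in males. With scan day as a block 1 was called in females, none of the 247, and 10 in males, all among the 14. In females the count was 140, 164 and 155 without GEM high 1, 2 and 3, 92 and 67 without GEM low 1 and 3, 95 without MIX high 1, and 71, 409 and 717 without MIX low 1, 2 and 3. In males it was 351 without MIX low 3, 22 and 9 without GEM high 3 and 1, and 8 without GEM low 2 or MIX high 1. 75th percentile scaling moved the median of all features in females at the low dose by -0.13.

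CBZ was tested against DMSO controls. In females all 3 high-dose arrays were scanned on day 2 and all 3 controls on day 3. High-dose changes in females therefore cannot be told apart from scan day within that sex. The rank product ran on the 399 features with p under 0.01 in the two-factor test, where chance gives 371. In females limma called 0 features (382 at an unadjusted p under 0.05; rank product 11 higher and 5 lower at the low dose, 8 and 11 at the high dose), and the named genes closest were spata6l with 15.87 ± 1.05 against 12.17 ± 1.59, zgc:92590 at -2.23 and the antigen presentation gene mhc2dgb at -2.12 (n = 3 each, adjusted p = 1). In males limma called 0 (2056 at an unadjusted p under 0.05; rank product 10 and 5, then 25 and 4). At the high dose the transcription factor gene foxo3b stood at 8.72 ± 0.25 against 11.09 ± 0.49, the muscle calcium store gene casq1a at 9.16 ± 0.84 against 6.83 ± 0.62 and palm3 at 3.04 ± 0.85 against 6.53 ± 0.72 (n = 3 each, F-test adjusted p = 0.275 each). With the replicate number as a block all 3 passed the high-dose contrast, by which 211 features rose and 68 fell, while the F test called 0. Without control 1 or CBZ high 2 all 3 passed that contrast too, as foxo3b and palm3 did without CBZ high 3. Cell cycle genes were higher in high-dose males by a median of 1.75 (23 of 27, adjusted p = 3.5e-08, and 0.973 with an estimated correlation), ccnb2 with 13.69 ± 1.96 against 8.77 ± 2.70. Ovary markers were higher beside them by a median of 4.93 (adjusted p = 0.395 with an estimated correlation; 24 of 25 higher, 21 passing over the list alone and 0 over all genes; btg4 with 13.44 ± 3.14 against 7.07 ± 3.13). Fatty acid oxidation genes (38 of 40 lower, -0.77) and respiratory chain genes (40 of 41 lower, -0.46) were lower there, as were phase I (-0.63) and phase II enzymes (-0.57), each with an adjusted p of 0.973 with an estimated correlation. At the low dose 8 of 9 egg yolk genes were higher in males (1.70, adjusted p = 4.9e-06, and 0.671 with an estimated correlation), vtg4 with 15.29 ± 1.35 against 12.86 ± 0.96, beside ovary markers at 2.59 (adjusted p = 0.434 with an estimated correlation). Females had higher cholesterol synthesis (0.39) and phase I genes (0.24) at the low dose. At the high dose they had lower heat shock genes (-0.31, 0.973 each with an estimated correlation), beside exocrine pancreas markers at -0.61 (adjusted p = 0.507 with it). The interaction called 0 in limma (828 at an unadjusted p under 0.05), and 0 and 231 in the two-factor test after adjustment and at p under 0.01. The count in males was 73 without control 1 and 17 without CBZ high 3, and for the interaction 1 without male CBZ high 3.

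WWE was tested against water controls. The rank product ran on the 368 features with p under 0.01 in the two-factor test, where chance gives 380. In males 6 features were called by the F test, 3 with a symbol, and none passed at a single dose (rank product 6 higher and 10 lower, then 1 and 3). They were si:ch211-80h18.1, with 6.16 ± 0.18 at the low dose against 4.08 ± 0.73 (F-test adjusted p = 0.00689) and a change of -1.56 at the high dose, and the sperm and cilia genes dcst1 (6.04 ± 0.09 against 3.66 ± 0.92) and drc1 (4.78 ± 0.53 against 3.33 ± 0.32; n = 3 each, F-test adjusted p = 0.0484 each). Testis markers moved with them, higher by 1.15 at the low dose and lower by -0.83 at the high dose (adjusted p = 0.189 and 0.395 with an estimated correlation). 7 of 8 egg yolk and oestrogen receptor genes were higher in males at both doses, by medians of 1.1 and 1.12 (adjusted p = 1.65e-05 and 1.33e-05, and 0.671 each with an estimated correlation). The high-dose values were 14.30 ± 1.21 against 12.24 ± 0.39 for vtg5 and 16.44 ± 0.96 against 14.82 ± 0.41 for vtg7 (n = 3 each, adjusted p = 0.00639 each over the list alone, and 1 over all genes). Acute phase genes were higher by 0.38 and 0.55 (37 of 42 at the high dose, adjusted p = 8.59e-07, and 0.671 with an estimated correlation), plasminogen, plg, with 16.24 ± 0.34 against 14.42 ± 1.08, and cell cycle genes were lower by -0.57 and -0.44 (adjusted p = 0.00434 and 0.0438, and 0.973 each with an estimated correlation). Male control 3 had an ovary score of 13.7 against 7.75 and 5.02 in the other male controls.

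In WWE females limma called 0 features (1559 at an unadjusted p under 0.05; rank product 12 higher and 4 lower, then 6 and 12), and aptx with 4.56 ± 0.39 against 6.82 ± 0.12, arl6 with 6.12 ± 0.44 against 3.18 ± 0.56 and irgf3 at -2.61 were closest (n = 3 each, F-test adjusted p = 0.267, 0.267 and 0.489). At the high dose 20 of 22 cholesterol synthesis genes were lower, by a median of -0.71 (adjusted p = 3.78e-06, and 0.973 with an estimated correlation), msmo1 with 12.37 ± 0.99 against 14.03 ± 0.53 (adjusted p = 0.0297 over the list alone). Heat shock genes were lower by -0.43 (38 of 46, 0.973 with an estimated correlation). Female WWE control 3 had an ovary score of 7.72, the lowest of all females, beside exocrine pancreas and intestine scores of 14.18 and 10.81 (12.56 and 9.96, and 12.35 and 5.58, in the other controls). The lists stood beside intestine markers lower by -3.52 and exocrine pancreas markers lower by -1.49 (adjusted p = 0.537 and 0.395 with an estimated correlation). The interaction with sex called 0 (381 at an unadjusted p under 0.05; two-factor test 0 after adjustment and 84 at p under 0.01). The count in males was 16 without control 3, 2 without control 1 or WWE high 1, 3 without WWE high 2 or WWE low 3, and 1 without WWE high 3, WWE low 1 or WWE low 2. It was 2 with scan day as a block. All male arrays were scanned on day 5, so that block takes no day difference out of them and does not test scan day. In females it was 1 without control 1 or WWE low 1 and 2 without WWE low 3, and for the interaction 1 and 6 without male control 2 and 3.

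**Figure D4:**
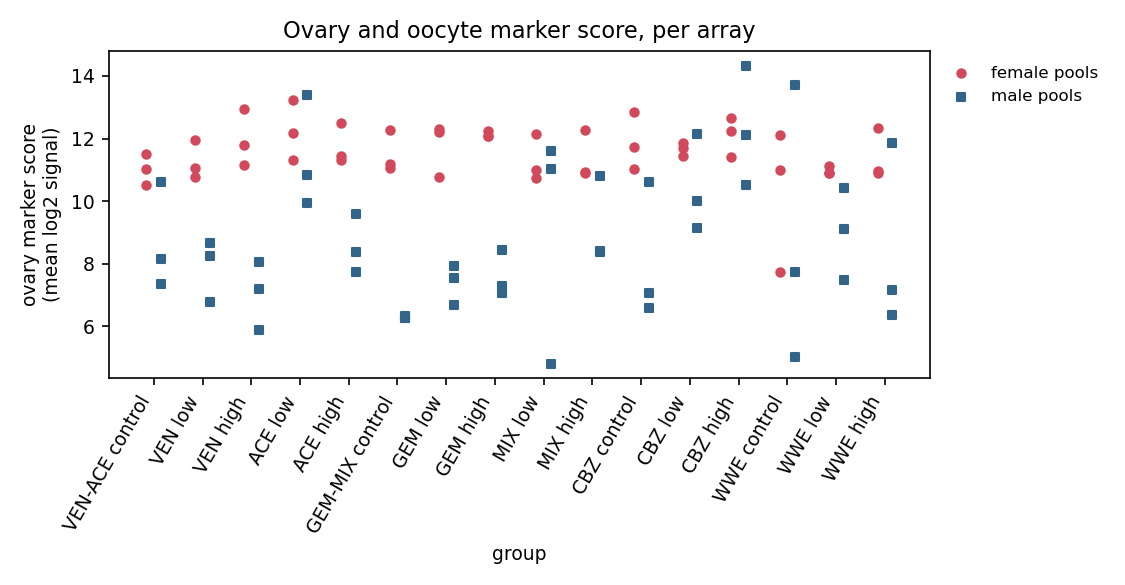
Each point is 1 array, placed by group (x axis) and by its ovary marker score, the mean log2 intensity of the ovary list (y axis). Female arrays ran from 7.72 to 13.23 with a median of 11.45, and male arrays from 4.81 to 14.33 with a median of 8.31.

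Of the 12 genes named in every comparison none passed in any exposure. With 1 array left out, cpt1b passed in low-dose ACE females without ACE low 1 (-4.91, adjusted p = 0.021) and, without VEN high 2, cpt1b (-3.52, adjusted p = 0.0266) and per1a (1.1, adjusted p = 0.0257) passed in high-dose VEN females. The smallest adjusted p was 0.166, for cpt1b in low-dose ACE females, and cyp3a65 in low-dose CBZ females stood at 11.92 ± 1.48 against 10.33 ± 1.35 (n = 3 each). vtg1 was not tested in GEM-MIX and WWE, where over 1 array had an outlier mark, nor hmgcra in WWE. Over all exposures 66 of the 504 pathway tests were called, 33 each way, where regrouped arrays gave a median of 67, and 0 with an estimated correlation (smallest adjusted p = 0.422). Cell cycle was called higher 10 times and lower 3 times, phase I enzymes 3 and 5, egg yolk 6 and 1, acute phase 4 and 1, cholesterol synthesis 4 and 1, phase II 1 and 4, heat shock 2 and 2, respiratory chain 1 and 2, fatty acid synthesis 1 and 0, and ribosomal proteins 1 and 0 (not with 75th percentile scaling). Fatty acid oxidation was called lower 6 times, the clock 3, glucocorticoid response 2, oxidative stress 2 and monoamines 1. With marker scores of other tissues as covariates 44 were called, 29 of them shared, with fatty acid oxidation called 1 time, cell cycle 5 (4 shared) and phase I enzymes 3 (2 shared). Bile acids, gluconeogenesis, growth hormone and IGF, lipoproteins, steroids and thyroid were never called. Of the marker tests 60 of 216 were called: ovary higher 11 times and lower 2, testis 6 and 3, exocrine pancreas 5 and 5, intestine 3 and 5, adipocyte and muscle 4 and 2, and lower alone for biliary (4), macrophage (4), endocrine pancreas (3) and erythrocyte (3). The smallest of their adjusted p with an estimated correlation was 0.0556. The change of a feature under ACE had a correlation across features of 0.61 at the low dose and 0.63 at the high dose between females and males. For the other exposures it was 0.04 to 0.33, and features are not independent replicates.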

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

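The tests of batch, scaling, single arrays and exposure and the regroupings of whole tanks were chosen after the results had been seen, and the other regroupings of the arrays were planned. Each share of regroupings, here and below, was judged on its own, without correction for the number of counts.

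The response to VEN differed between the sexes for 31 features by the interaction test, which brought it here. The count of called features, 976 in females and 0 in males, is a comparison of thresholds and does not test that difference. Of 100 groupings of the same arrays, the real one included, 5 gave an interaction count of 31 or more, with 86 the highest of the others, so chance cannot be excluded for it. When female and male arrays of the same treatment and number were moved together, as if from 1 tank, 1 of 100 did (highest other 13). That would exclude chance only if such arrays shared a tank, which the labels do not state. As this regrouping was chosen after the planned result, chance stays open. With the tank as a random block 183 features were called. For VEN in females 2 of 100 gave 976 or more, so chance can be excluded, but the highest other had 1440. That grouping set the VEN high arrays of slide 26 (replicates 1 and 3) and VEN low 3 in one group, so it follows the slide. With scan day as a block the high dose rests on VEN high 2 alone. For VEN in males 100 of 100 reached 0, with 205 the highest.

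The features called for VEN in females changed by a median of 2.1 in their called direction in high-dose females, where they were selected, and by 0.14 in high-dose males, a gap that selection widens. A batch of slide 26, which held 2 of the 3 high-dose arrays, stays open, since the 2 arrays on it without VEN deviated from their own groups by a mean of 0.65, one by 1.3 (GEM high 3) and one by 0.01 (WWE low 2). A shift of single arrays without any link to exposure stays open too, because 1 of 72 arrays without VEN, Female WWE low 1, deviated by 1.32. An effect of VEN may remain: the single high-dose array scanned on day 1 with its controls changed by 1.43, but these arrays helped to choose the features and their direction, so a positive value was expected. These explanations cannot be told apart with 2 arrays on the slide and 1 off it.

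The response to ACE differed between the sexes for 4 features by the same interaction test. 4 of 100 groupings gave as many, and the highest other had 272, many times the real count, which points to a structure of the samples. With 4 features and such a grouping, chance is not firmly excluded. With both sexes of a tank moved together 2 of 100 gave as many (highest other 4), and with the tank as a random block 25 were called. For ACE the real counts were 470 in females and 895 in males. 2 and 1 of 100 groupings gave as many, with 570 and 580 the highest others, and 1 of 100 did for VEN against ACE in each sex, with 1746 and 998. Chance can be excluded for each, but the real grouping nearly follows scan day, and in both highest groupings of VEN against ACE the high-dose VEN and ACE arrays only traded names. These 4 counts with scan day as a block were 0 (limma, 1573 at an unadjusted p under 0.05), 23, 58 and 5.

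The 1056 features called for ACE in either sex, 309 in both, moved by a median of 1.82 between the ACE arrays of days 2 and 3 and their controls of day 1. A batch of scan day and slide has what it needs: between 11 unexposed controls of other experiments on days 2 and 3 and 10 VEN arrays on day 1 the same features differed by a median of 1.8, 934 of them in the same direction. Acetaminophen as the whole cause is argued against, since ACE arrays differed from those unexposed controls of the same days by 0.08 (SD between the control arrays 0.20). Scaling between arrays as the cause is argued against, since quantile scaling called 894 features in males and 75th percentile scaling 987, 816 and 772 of them among the 895. A smaller effect of ACE, and any difference in handling before the scan, stay open. The 11 other controls held DMSO while VEN and ACE were given in water, so solvent and experiment differed along with scan day. The WWE water controls, all of day 5, had a mean level of -1.22, near the -1.3 of the VEN-ACE controls. Slides 25 and 26, of days 5 and 6, held exposed arrays in both solvents. Their DMSO arrays had levels of -0.35, -0.01 and -0.34, and their water arrays 0.17, 0.05, -0.25, -0.44 and -0.59. DMSO controls of day 2 had a mean of 0.73. For the arrays of these slides the values argue against solvent as the source of the difference.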

How the results depend on the processing

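The contrasts over both sexes and doses, the slide and scan day blocks for the pathway lists, the marker scores as covariates and the fit without 8 arrays with outlying ovary markers were chosen after the data had been seen, and the other alternatives were planned. Signal over background limited depth: on an array 41.7% to 77.5% of probes were well above background, and many called features had control arrays below it. Of 90 named changes that passed, 82 kept direction and call with quantile scaling, 77 with 75th percentile scaling, 61 with normexp, 86 without a filter, 74 in the authors' value table, 26 with scan day and 20 with slide as a block, and the cause was not tested except where stated. Under the replicate block 85 kept them, and 4 that had not passed did, trim62.1 in low-dose MIX females (-2) and foxo3b (-2.37), casq1a (2.32) and palm3 (-3.49) in high-dose CBZ males. The WWE count in males was then 2 (6 in the main model). Arrays with the same replicate number in an experiment had mean correlations of their deviations from the group mean of 0.01 in VEN-ACE, 0.01 in GEM-MIX, 0.25 in CBZ and 0.16 in WWE, over 0.1 in 19 of 60, 23 of 60, 14 of 18 and 12 of 18 pairs. Since this did not hold for every pair, the numbers were not taken to pair samples, though in CBZ and WWE arrays with different numbers had means of -0.12 and -0.08. Counts below are features called, with the main count in brackets at its first mention.

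With 75th percentile scaling the VEN interaction with sex called 6 (31), the ACE interaction 0 (4), GEM against MIX 129 in females (247) and 8 in males (14), WWE in males 1 (6), the pathway lists 104 (66), and the sex difference of fabp10a turned to 0.58 (-0.13). Quantile scaling gave MIX males 2 (1), WWE males 2 and the WWE interaction 1 (0). With normexp the counts were VEN females 526 (976), VEN interaction 0, ACE females 306 (470), ACE interaction 1, GEM females 0 (1), GEM males 1 (0), MIX males 12, GEM against MIX in males 31, CBZ males 1 (0), WWE males 43 and WWE interaction 7. The authors' value table gave VEN interaction 0, ACE males 1354 (895), ACE interaction 0, GEM females 0, GEM against MIX 129 in females and 4 in males and 673 over both sexes and doses (1078), and WWE males 2.

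The strict filter tests fewer and brighter features. It gave VEN females 2, VEN interaction 0, ACE females 108, ACE males 225, ACE interaction 1, VEN against ACE 426 in females (2410) and 1010 in males (2141), GEM females 13, MIX males 0, GEM against MIX in females 380, WWE males 0, the sex difference 3794 (6767) and GEM over both sexes and doses 100 (62). Without a filter VEN females had 1570 and GEM against MIX in females 142, and every probe on its own gave the VEN interaction 19.

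Scan day as a block gave VEN females 201, VEN interaction 10, ACE females 0, ACE males 23, ACE interaction 2, VEN against ACE 58 in females and 5 in males, GEM females 0, MIX females 2 (0), MIX males 0, GEM against MIX in females 1, WWE males 2, and over both sexes and doses GEM 4 and GEM against MIX 211. Where female high-dose VEN arrays enter, scan day as a block leaves VEN high 2 alone to carry that dose. In WWE all male arrays were of day 5, so that block takes no day difference out of male contrasts. Slide as a block left 8 residual degrees of freedom in VEN-ACE, 6 in GEM-MIX, 3 in CBZ and 7 in WWE. It gave VEN females 0, VEN interaction 0, ACE females 204, ACE males 20, ACE interaction 0, VEN against ACE 5 in females and 3 in males, GEM females 0, GEM against MIX 0 in females and 1 in males, WWE males 0, and over both sexes and doses GEM 0 and GEM against MIX 0. With it 6 changes reversed: in high-dose VEN females adarb1a -0.37 (5.14), the uncharacterised predicted gene -1.16 (4.44), gdf11 -1.21 (4.28) and abcc2 0.86 (-4.80), in males dcbld1 at high VEN against ACE 0.07 (-4.19), and cry3b over both sexes and doses in GEM against MIX 0.17 (-0.74). The tank as a random block gave the VEN interaction 183, the ACE interaction 25, GEM females 7 and the WWE interaction 1.

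With the arrays of 1 sex alone VEN females had 196, ACE females 285, GEM females 0, MIX males 0 and WWE males 0, each from fewer residual degrees of freedom. Marker scores as covariates gave VEN females 1468, VEN interaction 8, ACE females 164, ACE males 376, ACE interaction 0, VEN against ACE in males 354, GEM females 6, MIX females 1, MIX males 2, GEM against MIX 56 in females, 3 in males and 193 over both sexes and doses, and WWE males 0. Without the 8 arrays the VEN interaction had 18, MIX males 23, CBZ males 4 and WWE males 13. With an estimated correlation 0 pathway lists were called. The methods' two-factor test spans both sexes, both exposures of an experiment and sex interaction, and gives a single count per experiment. At p under 0.01 it called 4522 features in VEN-ACE, 1348 in GEM-MIX, 399 in CBZ and 368 in WWE, where chance gives 419, 416, 371 and 380. After adjustment it called 4377 in VEN-ACE, 299 in GEM-MIX, 0 in CBZ and 1 in WWE.

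Leaving out each array in turn gave ranges of 165 to 3375 for VEN females, 0 to 19 for VEN males, 5 to 984 for the VEN interaction, 190 to 807 and 500 to 945 for ACE females and males, 2 to 9 for the ACE interaction, and 1526 to 4072 and 1235 to 2857 for VEN against ACE in females and males. They were 0 to 11 for GEM females, 0 to 0 for GEM males and the GEM interaction, 0 to 195 and 0 to 381 for MIX females and males, 0 to 216 for the MIX interaction, and 67 to 717 and 8 to 351 for GEM against MIX in females and males. They were 0 to 0 for CBZ females, 0 to 73 for CBZ males, 0 to 1 for the CBZ interaction, 0 to 2 for WWE females, 1 to 16 for WWE males and 0 to 6 for the WWE interaction. Over both sexes and doses they were 40 to 72 for GEM and 625 to 1504 for GEM against MIX. The sex difference ran from 5929 to 8275 and the pathway lists from 58 to 76.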

Other observations

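The contrasts over both sexes and doses, the regroupings for them and the tests of ovary tissue, oestrogen, female livers, exposures and tanks were chosen after the data had been seen, and the other regroupings were planned.

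Averaged over both sexes and doses, 5 of the 26 circadian clock genes tested were lower under GEM. As a list the clock was not called in GEM females (medians -0.19 and -0.18, adjusted p = 0.549 and 0.353). The period gene per2 fell by 2.5 (12 exposed against 6 control arrays, SE 0.38, adjusted p = 0.00224), a 5.65-fold decrease, from 8.37 ± 0.61 in female controls to 6.13 ± 0.45 and 5.13 ± 1.21 at the low and high dose, and from 9.25 ± 1.06 to 6.90 ± 1.09 and 7.09 ± 0.65 in males (SD, n = 3 each). The cryptochromes cry5 (-1.47, adjusted p = 0.00396), cry1b (-1.34, adjusted p = 0.0142) and cry3b (-0.86, adjusted p = 0.0288) and the clock output factor tefa (-0.85, adjusted p = 0.0279) fell too, and 9 passed adjusted over the list alone. The cell cycle inhibitor hbp1 (-1.52, SE 0.21, adjusted p = 0.00122), gch1, the first enzyme of tetrahydrobiopterin synthesis (-1.65, adjusted p = 0.00223), msrb3 (-1.01) and slc25a48 (-1.43) fell. The aromatic amino acid transporter slc16a10 (1.12, SE 0.16, adjusted p = 0.00122), kctd12.1 (1.14, adjusted p = 0.00136), the cytokine receptor-like crlf1a, at a log2 change of 1.2, the mitochondrial fusion gene mfn2 (1.03) and odc1, the first enzyme of polyamine synthesis (2.03, adjusted p = 0.00801), rose. In all 62 of 20904 features were called, 16 higher and 46 lower, 38 with a symbol. All 62 had the same direction in both sexes at both doses, which their selection on the average of these differences favours. The named genes kept their direction under the other scalings. The SEs and adjusted p over both sexes and doses take female and male pools of the same treatment and number as independent. Such pools deviated together (mean correlation 0.12 in GEM-MIX), and the tank as a random block was not fitted to these contrasts.

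GEM differed from MIX, which contains gemfibrozil, over both sexes and doses for 1078 features (683 higher, 395 lower under GEM), among them slc16a10 (1.34, adjusted p = 2.96e-06), cry5 (-1.76, adjusted p = 2.11e-05) and per2 (-2.44, adjusted p = 0.00017). Scan day as a block called 211, 196 of them shared, slc16a10, cry5 and per2 included. For GEM against control that block called 4, all among the 62, with hbp1 at -1.59 (SE 0.25) and per2 at -2.69 (SE 0.42) among them, and all 62 kept their direction. Of the 5 clock genes per2 alone stayed called. The calls of cry5 (-1.57, SE 0.30, from -1.47, SE 0.24), cry1b (-1.42, SE 0.32, from SE 0.25), cry3b (-0.78, SE 0.23, from SE 0.18), tefa (-0.76, SE 0.22, from SE 0.17) and slc16a10 (0.95, SE 0.18, from 1.12, SE 0.16) ended, with 1224 features at an unadjusted p under 0.05. Slide as a block called 0 in both. The GEM count was 40 without Female GEM-MIX control 1 and 41 without control 3, and that against MIX 712 without Female MIX high 1, 701 without Male GEM high 2, 659 without Male GEM low 1 and 625 without Male MIX high 1. The labels give no sampling time of day, which clock transcripts follow. 1 of 100 groupings of the arrays within each sex called 62 or more for GEM (highest other 1) and 1 of 100 called 1078 or more for GEM against MIX (highest other 44). Chance can thus be excluded for arrays taken as independent. When both sexes of a tank number were moved together, 2 of 84 groupings, the real one included, called as many as the real one. The highest other, which set control 1, control 3 and GEM high 3 as the reference, called 130. The share is small, but with a higher count from another grouping chance is not firmly excluded for GEM, and a difference between tanks may add to the count. Moved in this way for GEM against MIX, 1 of 100 groupings called 1078 or more and the highest other 761, one that exchanged GEM high 3 with MIX high 2 alone, so chance can be excluded.

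Over both sexes and doses limma called 1979 features for ACE and 6596 for VEN against ACE, but 0 and 3 with scan day as a block, which called 2 for MIX. It called 0 for VEN, MIX, CBZ and WWE, with 2396, 1650, 807 and 1462 features at an unadjusted p under 0.05. The VEN count was 290 with 75th percentile scaling, 123 without Female VEN high 2, 20 without Female VEN low 2, 14, 6 and 2 without Male VEN high 3, Male VEN-ACE control 2 and Male VEN low 1 and 3 without Female VEN-ACE control 3, the MIX count 177 without Male MIX low 3 and 89 without Female MIX low 3, the WWE count 8 without Female WWE low 1 and the ACE count 1306 without Female VEN-ACE control 1. As many were called by 1 of 100 groupings for ACE (highest other 662) and 1 of 100 for VEN against ACE (2152), where the real grouping nearly follows scan day, and by 100 of 100 for VEN (977), MIX (460), CBZ (142) and WWE (29).

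Transcripts of ovary stood high in some male liver pools. The 8 male arrays below were picked on 13 markers and are not the same set as the 8 arrays left out above, which held Female WWE control 3. 8 of 48 male arrays, 1 of them a control, reached the female median on 13 ovary markers, and the 13 markers held out were higher in them by a median of 5.37 (12 of 13 higher) than in the other 40 male arrays, which is consistent with ovary tissue in those pools; of the most abundant markers, the egg coat genes zp3 and zp3.2 stood at 16.08 and 15.65 against 10.48 and 10.23 (females 14.8 and 14.6) and cldnd at 15.39 against 9.6, while rnasel2, also high in livers of both sexes, stood at 16.52 against 16.64. An oestrogen response of male liver is argued against, since esr1 differed by -0.24 (6.94 against 7.18; permutation p = 0.35, females 11.5), and female livers in male pools are argued against, since vtg2 differed by -0.18 (5.71 against 5.89; permutation p = 0.807, females 13.43). Whether the exposures contribute stays open: the spread of the score between groups had a permutation p of 0.145. The highest male score, 14.33, lay above the highest female score, 13.23, and in male arrays the score of 25 cell cycle genes outside the ovary list followed it (r = 0.88 and rho = 0.81, permutation p = 1e-05 each, the smallest the permutations can give; r = 0.84 without the 2 farthest arrays, and 0.83, 0.84, 0.92 and 0.93 within VEN-ACE, CBZ, GEM-MIX and WWE).

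Female and male pools of the same treatment and replicate number deviated together from their groups, with a mean correlation across features of 0.16 over 48 pairs (38 above 0), 0.18 for pairs on different slides and 0.20 for 18 pairs on different days. A shared tank is a candidate explanation (one-sided permutation p = 1e-04, the smallest the permutations can give), and the labels do not state which samples shared tanks. Permuted numbers cannot separate a tank from anything else tied to the replicate number. Arrays of the same sex and number but another treatment had means of 0.25 in CBZ and 0.16 in WWE. The female and male pairs had 0.22 and 0.05 there. In VEN-ACE and GEM-MIX these means were 0.01 each, against 0.22 and 0.12 for the pairs.

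The liver exporter gene abcc2, singled out after its values were seen, stood below 4 on 7 female arrays, 4 of them VEN and 3 WWE, 1 of these a WWE control. The 3 WWE arrays were replicate 1 of the control, low and high groups. WWE females ran from 2.11 to 10.28, and the lowest male array had 5.21.

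For the other counts, the groupings of the same arrays that called as many features as the real one were 24 of 100 for GEM in females (real 1, highest other 59), 100 for GEM in males (0, 8) and for the GEM interaction with sex (0, 1), 100 for MIX in females (0, 1196), 12 for MIX in males (1, 450), 100 for the MIX interaction (0, 371), 14 for GEM against MIX in females (247, 1503) and 2 for it in males (14, 21). They were 100 for CBZ in females (0, 1), in males (0, 809) and for the interaction (0, 223), 100 for WWE in females (0, 42), 5 for WWE in males (6, 190) and 100 for the WWE interaction (0, 1). They were 1 for the sex difference (6767, 1) and 57 for the pathway lists (66, 98, with a median of 67). Chance can be excluded for the sex difference and for GEM against MIX in males, and not for the others. Where another grouping called several times the real count, it points to a structure of the samples. The highest for MIX in females set 3 arrays of slides 12 and 20 together, and that for GEM against MIX in females gave 3 arrays of those slides to GEM, in 2 groups, and the highest for MIX, CBZ and WWE in males largely sorted the arrays by ovary score. The counts with scan day as a block were 2 for MIX in females, 1 for GEM against MIX in females, 0 for MIX in males, 0 for CBZ in males and 2 for WWE in males. The last does not test scan day, since all male WWE arrays were scanned on day 5.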
